A study of Drosophila melanogaster with 2 samples.

How the data were processed

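The samples were 2 replicates of whole embryos aged 0 to 16 h from a line stably expressing GFP-tagged BuGZ, processed for chromatin immunoprecipitation, with sonicated chromatin of 200 to 800 bp per the labels' protocols. Each was used as a library of the single group, numbered as in the labels. Aligner, peak caller, their versions and the reproducibility threshold are not given in the sources used here. Per the deposited read-me texts, each replicate's candidate list was called by the authors from that replicate's alignment to dm6 against a control alignment, the pooled list from both, and the reproducible list by a threshold on the irreproducible discovery rate (IDR) of those lists. The sample descriptions name the libraries input controls, in conflict with the antibody label and with these parent files. Signal tracks and alignments were not analysed here.

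The deposited lists are narrowPeak intervals. The signal value of each region is the authors', on a scale not stated and with a different range in each list (15.4 to 890 for replicate 1, 15.5 to 660 for replicate 2, 25.7 to 1538 pooled), so it served only to rank regions within a list. The deposited -log10 q-value is at a ceiling for strong regions and the same for every reproducible peak, and was not used; the p-value column holds no values. The summit offset, in bp, gave the summit position, which for most regions is the middle of the interval. Median widths were 290 bp for replicate 1, 376 bp for replicate 2 and 336 bp pooled. Of the 2413 reproducible intervals, 3 repeat an earlier interval with another summit, and 31 adjacent pairs overlap; all were kept. The lists give no read depth. Each candidate list ends at 30000 regions, so its lowest regions are background by construction, and a region missing from it may only have ranked lower.

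Coordinates are dm6 (Release 6 of the genome), 1-based, and every interval was checked to lie within its chromosome. Genes and transcript starts came from the Ensembl annotation of the same assembly on 7 main chromosomes (X, Y, 2L, 2R, 3L, 3R and 4), with transposable elements left out: 18277 genes, 13968 of them protein-coding, and 23694 distinct TSS positions. A summit within 250 bp of a TSS was a promoter summit, and other summits were classed in the order 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic. A gene had a peak where a reproducible summit lay within 250 bp of any of its TSS, so a peak in a shared promoter counted for each gene there. Background regions were the 14890 pooled candidates of the lower-ranked 50% that overlap no reproducible peak. Motifs and GC content were taken within 100 bp of the summit and words within 50 bp, on both strands. For these, 3503 of these were sampled to the peaks' share of promoter summits. Signal values of promoter and distal peaks were compared within the reproducible list.

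Before the data were examined, 21 gene lists, 18 motifs, the tests and most alternatives were fixed, together with the rule for named genes: the 25 strongest peaks with all genes within 250 bp or else the nearest, BuGZ, up to 4 members per gene list by signal value, every motif, and the 10 words of 6 bases with the smallest p. The ribosomal protein genes without a peak and the genes of the closing section were named after their values were seen. Lists defined by symbol patterns include paralogs of restricted expression. Of the listed symbols, 2 were brought to their current names by hand, and 1 was not found in each of 5 lists. Regions of the replicates were matched where their summits lay within 200 bp. Fisher's exact test, two-sided, compared shares, with Benjamini-Hochberg adjustment over lists, motifs, words or classes. Exact binomial tests compared 6 chromosome arms with their share of TSS positions and of sequence length, and permutation tests used 100000 resamples. Intervals are 95% Wilson for shares and 95% Woolf for odds ratios. All of these treat peaks or genes as units; with 1 group of 2 replicates no test between samples was possible, and replicate spread is shown by repeating each result on the top 2413 regions of each replicate alone. Whether the replicates came from separate collections of embryos is only as the labels state.

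Alternatives covered other promoter and summit windows, other overlap criteria, other backgrounds, protein-coding genes only, genes sharing a peak merged, the stronger part of the reproducible list, each replicate alone, and, added after seeing the data, a GC-matched background of 2377 regions, the peaks in the top 2413 of both replicates, background promoters for divergent pairs, and annotation classes among non-promoter regions. The flanking background was the sequence 400 to 600 bp to the left of each summit.

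The tests were tested on simulated data. A gene list planted at 60% among 18277 genes with random hits was called in 50 of 50 rounds, with 0.2% of the other lists called. Hits were drawn gene by gene, whereas neighbouring genes in the data can share a peak. The planted share also exceeded that of every called list except ribosomal proteins. These rounds therefore do not give the power or false-call rate for the lists reported below. For 2080 words of 6 bases, all 3 within a planted word were called and 8 others, 6 of which overlapped its edge. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.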

Results

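Chromatin immunoprecipitation with sequencing was carried out on whole embryos, aged 0 to 16 h, from a transgenic Drosophila melanogaster line that expressed BuGZ (CG17912) with a green fluorescent protein tag at its C terminus. BuGZ is a zinc finger protein known to bind the spindle checkpoint protein Bub3 and to act at kinetochores and the mitotic spindle. The series held 1 group of 2 replicates, so no condition was compared with another. The question addressed was where in the genome the tagged protein was recovered, and at which genes and sequences. The deposited lists were 30000 candidate regions for each replicate, 30000 for both replicates pooled, and 2413 reproducible peaks drawn from these. The number of sequenced reads behind the lists was unknown here, so intervals below cover counting error over peaks or genes only. Each sample's own description called it an input control, whereas its antibody label and the parent files of its peak list pointed to an immunoprecipitate set against a separate control. The libraries were treated as immunoprecipitates, and this reading is unsettled.

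The strongest peaks lay at the same genes in both replicates. CG14100 on 3L carried the highest peak (19590464 to 19590784, dm6), with a signal value of 1538, and it ranked 1 in the list of each replicate. Next came lncRNA:CR31840 on 2L (signal value 1100) and Alg3, a mannosyltransferase of protein glycosylation, on 2R (signal value 999). These signal values are the authors' own, compared only within the reproducible list, whose median was 134 and range 101 to 1538. Of the 25 strongest peaks, 16 had their summit within 250 bp of an annotated transcription start site (TSS), 5 lay in introns and 4 between genes, and all 25 ranked within the first 43 regions of replicate 1 and the first 54 of replicate 2. The promoter peaks among them lay at mRpL41, Nup37 with RpS27 and sisRNA:CR46364, Art3 with mRpS10, CG1888, CG18549, Gapdh2, Ugalt, CG11309 with CG7632, CHMP2B with Tcs5, Pal1 with Pdrg1, px, CG1635, and Uhg4 with snoRNA:Psi28S-2949. Gapdh2 encodes a glycolytic dehydrogenase, Nup37 a nuclear pore protein and Ugalt a sugar transporter of the Golgi. The intronic peaks lay in CG11050, CG9663, ph-p, Lk6 and sbb by nearest TSS, the last of these 20111 bp from it. The intergenic ones were nearest to jp (746 bp), sp3 (581 bp), CG6966 (262 bp) and lncRNA:CR44761 (4727 bp).

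Below these strongest sites the replicates ranked regions less alike. Among the 2413 highest regions of each replicate's own list, 1359 (56.3%, 95% Wilson interval 54.3 to 58.3) had a summit within 200 bp of such a region in the other replicate. Random draws of 2413 regions from the replicate 2 list matched 8.37% of the replicate 1 regions on average (range 7.34 to 9.32 over 20 draws). Counting only summits within 50 bp lowered the shared part to 40.5%. With summits within 200 bp it was 58.6% for the top 1206 regions and 56.8% for the top 4826, so it changed little with list length. Of the reproducible peaks, 2368 (98.1%) had a region somewhere in both replicate lists, 1355 were among the top 2413 of both, 527 of replicate 1 only, 447 of replicate 2 only and 84 of neither. Ranks by signal value in the replicates had a Spearman's rho of 0.58 over the 12033 regions shared by their lists and of 0.36 over 2368 reproducible peaks, a narrower range of signal. Both are over regions, which are not independent replicates. The reproducible list was identical to the 2413 regions of highest signal in the pooled list, so membership did not require a high rank in each replicate.

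Promoters were the main site of the reproducible peaks. Summits of 1357 of the 2413 peaks (56.2%, 95% Wilson interval 54.2 to 58.2) lay within 250 bp of a TSS, against 1970 of 14890 background regions (13.2%), the lowest-ranked candidates of the same libraries. The odds ratio was 8.43 (95% Woolf interval 7.68 to 9.25; log10 p = -435, two-sided Fisher's exact test), and the promoter share was 54.5% for the top regions of replicate 1 and 56.7% for those of replicate 2. Coding exons held 16 peaks (0.66%) against 16.8% of background regions (adjusted p = 7.1e-149, Fisher's exact test), and 3' UTRs held 20 (0.83%) against 3.64% (adjusted p = 1.2e-16, Fisher's exact test). Introns held 687 peaks (28.5% against 45.5%, adjusted p = 9.8e-57) and intergenic sequence 264 (10.9% against 17.5%, adjusted p = 1.2e-16, both Fisher's exact test). These lower intron and intergenic shares follow from the higher promoter share. Among non-promoter regions alone, compared after the data had been seen, introns held 65.1% of peaks against 52.4% of background (adjusted p = 4.1e-15), intergenic sequence 25% against 20.1% (adjusted p = 0.000333) and coding exons still only 1.52% against 19.4% (adjusted p = 1.1e-69, all Fisher's exact test). The share of 3' UTRs was also still lower there (1.89% against 4.20%, adjusted p = 0.000168, Fisher's exact test). Shares in 5' UTRs outside promoters (1.57% against 2.01%) and in other exons (1.28% against 1.40%) did not differ past the threshold (adjusted p = 0.206 and 0.778, Fisher's exact test). Among non-promoter regions both were higher at peaks (3.6% against 2.31% and 2.94% against 1.61%, adjusted p = 0.012 and 0.0034, Fisher's exact test). Along the pooled candidate list, the promoter share went from 55.1% in the 3000 regions of highest signal to 10.8% in the 3000 of lowest signal.

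**Figure D1:**
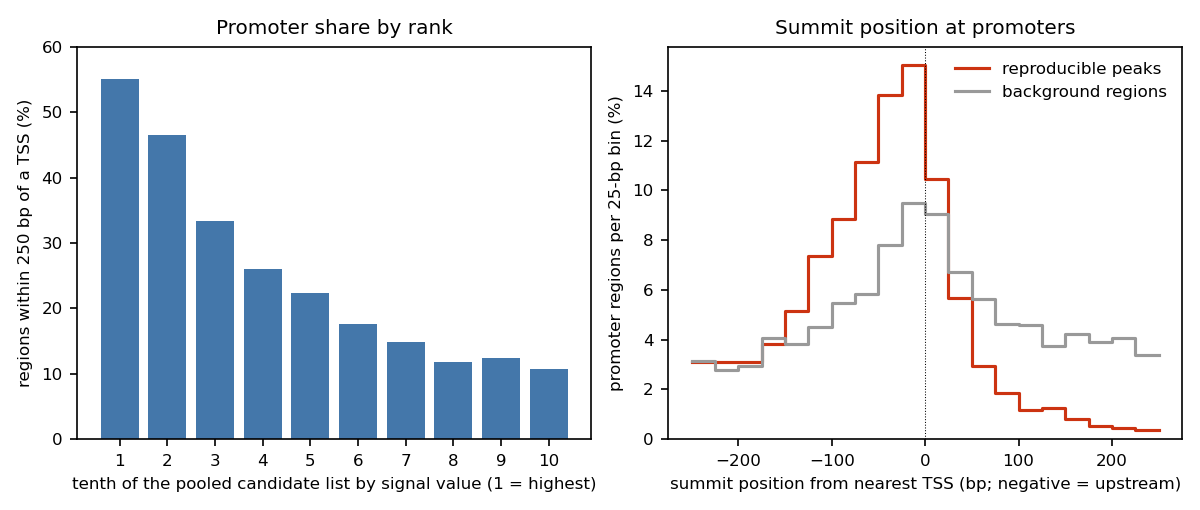
Left, the percentage of regions with a summit within 250 bp of a TSS (vertical axis) in successive groups of 3000 regions of the pooled candidate list, ordered by signal value (horizontal axis), from 55.1% in the first group to 10.8% in the last. Right, the position of the summit from the nearest TSS in bp, negative upstream, as the percentage of promoter regions per 25-bp bin, for 1357 reproducible peaks and 1970 background regions.

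At promoters the summits lay mostly upstream of the start site, with a median position of -43 bp (interquartile range -103 to 1 bp). The part upstream was 74.5% of 1357 promoter peaks (76.8% for replicate 1 and 66.6% for replicate 2), against 49.9% of promoter background regions (odds ratio 2.93, p = 4.1e-47, two-sided Fisher's exact test). This position was computed after the data had been seen. Divergent gene pairs, whose start sites lie within 1000 bp on opposite strands, were the site of 687 promoter peaks (50.6%), against 34.9% of all genes (odds ratio 1.91, p = 4.2e-30, two-sided Fisher's exact test). Against the promoter regions of the background, of which 28.3% lay at divergent pairs, the odds ratio was 2.60 (p = 5.9e-39, Fisher's exact test), a comparison added after the data had been seen. A summit between the start sites of a divergent pair counts as upstream of whichever is nearer. The upstream share and the divergent share are therefore not separate findings, and their contributions were not told apart. Within the reproducible list the median signal values of promoter and distal peaks were 134.4 and 134.0 (difference 0.46, p = 0.773, two-sided permutation test with 100000 resamples). All these peaks were selected by a signal value of at least 101, so this says nothing of candidate regions at large, among which the promoter share rose with signal.

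Cytosolic ribosomal protein genes stood far above every other gene list. A reproducible peak lay within 250 bp of a TSS at 73 of 90 of these genes (81.1%, 95% Wilson interval 71.8 to 87.9), against 9.07% of all other genes (odds ratio 43.0, adjusted p = 1.3e-57, two-sided Fisher's exact test). The share was 76.7% with replicate 1's own top regions and 83.3% with those of replicate 2. RpS27 (signal value 901, summit 17 bp from its TSS), RpL7 (signal value 569), RpL13A (signal value 500) and RpL34b (signal value 469) carried the highest peaks of the list. Among the 17 without a peak were the tissue-restricted paralogs RpL22-like, RpS5b and RpS19b, and also RpS3, RpL6, RpL21 and RpLP2. Of the 17, 11 had a lower-ranked candidate region at the promoter. All genes together numbered 18277, of which 1723 (9.43%) had a peak.

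Further genes of protein synthesis and energy supply also carried peaks more often than other genes. Of the translation factors, 12 of 34 had one (35.3%, adjusted p = 0.000152, Fisher's exact test): eIF6 (signal value 548), eEF1gamma (395), eEF2 (288) and eEF1alpha1 (247) led by signal value. Oxidative phosphorylation genes followed with 18 of 80 (22.5%, adjusted p = 0.00134, Fisher's exact test), with ATPsynbeta, ND-51, ATPsynO and UQCR-Q at signal values of 208, 178, 170 and 162. Among genes with a candidate region at a promoter this call ended (odds ratio 1.82, from 2.81; adjusted p = 0.16, Fisher's exact test). Mitochondrial ribosomal protein genes had peaks at 15 of 73 (20.5%, adjusted p = 0.00857, Fisher's exact test), led by mRpL41 (966), mRpS10 (774), mRpL23 (367) and mRpL24 (267) by signal value. This call depended on the setting: by nearest gene their share was 8.22% against 11.2% of other genes (adjusted p = 0.755), and in the stronger part of the list 8.22% against 4.87% (adjusted p = 0.276, Fisher's exact test). Splicing factors reached 9 of 36 (25%, adjusted p = 0.0109, Fisher's exact test), including SmD3 (signal value 187), B52 (166), U2af50 (159) and Sf3b1 (133). By nearest gene their share was 11.1% (adjusted p = 1, Fisher's exact test).

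Genes for chromatin proteins were also over-represented. Insulator and promoter factors had peaks at 7 of 22 promoters (31.8%, adjusted p = 0.00821, Fisher's exact test): Chro, known both from interband chromatin and from the spindle matrix (signal value 424), Dref, which binds the DNA replication-related element (373, a peak shared with RpL13, whose TSS is nearer, at 8 bp against 92 bp), Cp190, an insulator cofactor (309), and pzg (178) led by signal value. Counted by nearest gene at any distance, this list did not pass (27.3%, adjusted p = 0.0568, Fisher's exact test). Polycomb and trithorax genes reached 7 of 29 (24.1%, adjusted p = 0.0305, Fisher's exact test), led by the remodelling ATPase brm (signal value 424), the histone methyltransferase E(z) (250), Sfmbt (169) and Jarid2 (130). Replicate 1 alone placed 12 of the 29 (41.4%, adjusted p = 1.9e-05) and replicate 2 alone 7 (24.1%, adjusted p = 0.0298, Fisher's exact test). Among genes with a candidate region the odds ratio was 1.22, from 3.07 (adjusted p = 1, Fisher's exact test). With protein-coding genes only the call also ended (adjusted p = 0.168, Fisher's exact test), although the list's 24.1% still lay above the 11.6% of protein-coding genes with a peak.

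Kinetochore genes, the process BuGZ is best known for, were not over-represented, and for spindle genes the outcome depended on the setting. Of 32 spindle checkpoint and kinetochore genes, only cmet, a kinetochore motor, had a peak (signal value 110; 3.13%, adjusted p = 0.505, Fisher's exact test). Spindle and microtubule genes had peaks at 6 of 31 (19.4%, adjusted p = 0.107, Fisher's exact test), with Chro, alphaTub84B (signal value 221), wac (160) and Grip71 (149) the highest. Replicate 2 alone placed that list past the threshold (25.8%, adjusted p = 0.0144, Fisher's exact test) and likewise heat shock and chaperone genes (35.5%, adjusted p = 0.000331, Fisher's exact test), which had 6 of 31 members with a reproducible peak (adjusted p = 0.107, Fisher's exact test), among them Hsp83 (signal value 509), Hsc70-4 (460), Hsp110 (148) and Hsp27 (139). Cell cycle and replication genes had 6 of 33 (adjusted p = 0.185, Fisher's exact test), with RnrS, dup, CycB3 and Dp at signal values of 206, 184, 160 and 141. Proteasome subunit genes had 3 of 48 (Rpn6, Prosbeta1 and Rpt5; adjusted p = 0.816, Fisher's exact test). With genes that share a peak merged, spindle, heat shock and cell cycle genes passed the threshold (adjusted p = 0.0393, 0.0393 and 0.0483, Fisher's exact test). This merging joined only genes that had a peak, which by itself lowers the share among the genes they were compared with. The calls under merging are therefore no separate evidence for these lists. With a window of 1000 bp spindle genes (32.3%, adjusted p = 0.0144) and heat shock genes (35.5%, adjusted p = 0.00584) also passed, as did heat shock genes by nearest gene (29.0%, adjusted p = 0.0127, Fisher's exact test).

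At their promoters, developmental and tissue-specific genes did not carry peaks more often than other genes. Embryonic patterning genes had promoter peaks at 3 of 34, namely bcd (signal value 159), hry (150) and cad (128), neuronal differentiation genes at 2 of 23 (elav, signal value 386, and Syx1A, 112), muscle differentiation genes at 2 of 18 (Tm1, 121, and Mef2, 107) and early zygotic genes at 1 of 19 (Sxl, 123). None of these 4 lists differed past the threshold (adjusted p = 1 for patterning, neuronal and early zygotic genes and 0.846 for muscle, Fisher's exact test). Counted by nearest gene at any distance, patterning genes passed (29.4% against 11.1%, adjusted p = 0.00814) and muscle genes did not (27.8% against 11.2%, adjusted p = 0.0691, Fisher's exact test). This count gives more chances to genes whose start sites lie far from others, and gene spacing was not corrected for. No peak lay at any of 186 chemoreceptor genes (95% Wilson upper limit 2.02%, adjusted p = 1.7e-07, Fisher's exact test). Genes for tRNA had 9 of 295 (3.05%, adjusted p = 0.000152, Fisher's exact test), led by tRNA:Tyr-GTA-1-8, tRNA:Thr-AGT-1-4, tRNA:Pro-AGG-1-1 and tRNA:His-GTG-1-3. Their number was 5 (1.69%) in replicate 1 alone and 12 (4.07%) in replicate 2 alone. Genes for snoRNA had 11 of 257 (4.28%, adjusted p = 0.00751, Fisher's exact test), led by snoRNA:Psi28S-2949, snoRNA:Psi18S-920, snoRNA:Me28S-A774b and snoRNA:Or-aca2. The last 3 of these share their peaks with the ribosomal protein genes RpL10Ab, RpS12 and RpS6. With replicate 2 alone the call for snoRNA genes ended (6.61%, adjusted p = 0.238), and with a window of 1000 bp it turned, to 21.0% against 13.9% of other genes (adjusted p = 0.00584, Fisher's exact test). The TSS used for snoRNA genes was the annotated 5' end of the RNA, and whether transcription starts there was not examined. Their low share within 250 bp therefore cannot be read as a low share at their promoters. Spliceosomal and related snRNA genes had 3 of 32 (snRNA:7SKa, snRNA:U6:96Ac and snRNA:U1:95Ca; adjusted p = 1, Fisher's exact test). The 111 replication-dependent histone genes had none (adjusted p = 0.000152, Fisher's exact test), and none of them had a candidate region; whether reads could be placed in this repeated cluster was not analysed here. Compared only with the 7432 genes that had a candidate region at a promoter, 3 lists stayed past the threshold: ribosomal proteins (odds ratio 22.9, adjusted p = 3.4e-34), translation factors (adjusted p = 0.0488) and, on the lower side, snoRNA genes (adjusted p = 0.00579, all Fisher's exact test). Calls for insulator factors (odds ratio 2.58, from 4.50, adjusted p = 0.211), splicing factors (1.36, from 3.21, adjusted p = 0.843) and mitochondrial ribosomal proteins (1.24, from 2.50, adjusted p = 0.994) ended there (Fisher's exact test). Those for tRNA genes (80 genes, 0.417, from 0.299, adjusted p = 0.0561) and chemoreceptors (adjusted p = 0.339) also ended (Fisher's exact test). Only 9 chemoreceptor genes remained, still without a peak, so that loss cannot tell a weaker depletion from fewer genes. With the 1355 peaks that ranked in the top 2413 of both replicates, a choice made after seeing the data, the calls for mitochondrial ribosomal, oxidative phosphorylation, splicing, Polycomb and snoRNA genes ended (adjusted p = 0.383, 0.0911, 0.0911, 0.0558 and 0.0664, Fisher's exact test). Among protein-coding genes only, those for mitochondrial ribosomal proteins and splicing ended too (adjusted p = 0.0773 and 0.0811, Fisher's exact test). The shares of these lists (20.5% and 25%) still lay above the 11.6% of protein-coding genes with a peak.

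**Figure D2:**
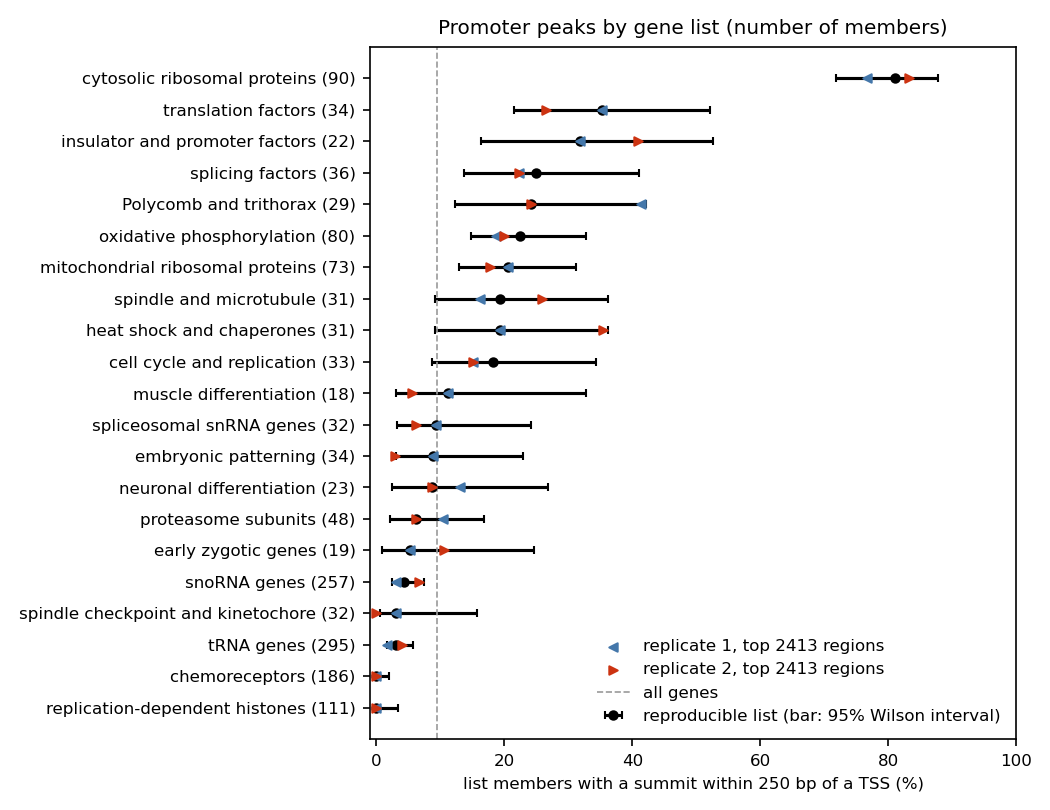
Percentage of each gene list's members with a summit within 250 bp of a TSS, for the reproducible list (circles, with 95% Wilson intervals) and for the top 2413 regions of each replicate (triangles); the dashed line marks all genes, 9.43%. Cytosolic ribosomal protein genes lie at 81.1%, and chemoreceptor and replication-dependent histone genes at 0.

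Sequences of housekeeping promoters and insulators were the most enriched motifs around the summits. The ZIPIC sequence AGGGYTG, bound by a zinc finger protein of insulators, occurred within 100 bp of 183 summits (7.58% against 2.65% of background regions with the same promoter share; odds ratio 3.01, 95% Woolf interval 2.33 to 3.88, adjusted p = 5.0e-17, Fisher's exact test). The DNA replication-related element TATCGATA occurred at 5.68% against 2.20% (odds ratio 2.68, adjusted p = 2.6e-11, Fisher's exact test), its core ATCGAT at 13.5% against 9.28% (odds ratio 1.53, adjusted p = 1.4e-06, Fisher's exact test) and the BEAF-32 element CGATA at 34.7% against 26.9% (odds ratio 1.45, adjusted p = 5.4e-10, Fisher's exact test). The core promoter sequence known as Ohler motif 7 occurred at 16.8% against 9.53% (odds ratio 1.91, adjusted p = 2.0e-15, Fisher's exact test) and Ohler motif 1 at 5.01% against 3.23% (odds ratio 1.58, adjusted p = 0.00132, Fisher's exact test). Some of these patterns overlap. Every TATCGATA holds ATCGAT and CGATA, and a word such as CAGCCCTG matches both ZIPIC and Ohler motif 7, so the same site can count for several motifs. Background regions come from the lower-ranked 50% of candidates, here and in the distal and promoter comparisons further below. Such contrasts cannot separate these sequences from other differences between strongly and weakly recovered sites, and accessibility was not measured here. GAGA repeats (7.05% against 4.42%; odds ratio 1.64, adjusted p = 4.3e-05), the su(Hw) core (1.91% against 0.999%; odds ratio 1.93, adjusted p = 0.00751) and the TATA box (18.2% against 14.0%; odds ratio 1.36, adjusted p = 4.7e-05) were also more frequent at peaks (Fisher's exact test). The Initiator occurred less often, at 15.7% against 21.3% (odds ratio 0.689, adjusted p = 2.4e-07, Fisher's exact test), as did runs of 8 adenines (8.33% against 10.5%; odds ratio 0.774, adjusted p = 0.00881, Fisher's exact test). Zelda, Pho, CA repeat, DPE, CTCF core, E-box and Ohler motif 6 sequences did not differ past the threshold, with odds ratios of 0.923, 0.970, 1.04, 0.817, 0.883, 1.11 and 1.71. Some calls differed between the replicates. With replicate 2 alone the odds ratio of the runs of adenine was 1.02 (adjusted p = 0.878), and Ohler motif 6 (2.30, adjusted p = 0.0123) and CTCF core (0.756, adjusted p = 0.00867, Fisher's exact test) passed the threshold. With replicate 1 alone the TATA box did not pass (1.16, adjusted p = 0.0741) and the E-box did (1.19, adjusted p = 0.041, all Fisher's exact test). Within 50 bp of the summit GAGA repeats (1.05), Ohler motif 1 (1.45) and su(Hw) core (1.39) no longer passed (adjusted p = 0.907, 0.0578 and 0.432, Fisher's exact test), nor did the Initiator against sequence beside the same peaks (0.864, adjusted p = 0.0823, Fisher's exact test). Against that sequence Ohler motif 6 (5.03, adjusted p = 0.00271), E-box (1.36, adjusted p = 0.00124) and Pho (1.34, adjusted p = 0.00476) passed (Fisher's exact test).

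Peaks were richer in A and T than the background, and so were most of the words that led an open search against it. Mean GC content within 100 bp of the summit was 40.9% ± 7.58 (SD over 2413 peaks) against 44.8% ± 8.07 (SD over 3503 matched background regions), a difference of -3.97 percentage points (p = 1e-05, the smallest that 100000 permutations can give). This background was matched on promoter class only. Among non-promoter regions, coding exons held 19.4% of background and 1.52% of peaks, and this difference was not separated from base composition or word frequency. In an open search within 50 bp of the summit over 2080 words of 6 bases, 271 were more and 375 less frequent at peaks (Fisher's exact test, Benjamini-Hochberg adjustment). The 10 with the smallest p were AAATAT (23.7% of peaks against 12.9%), TAAATA, AATATT, CCAGGA, ATATTA, ACACTG (11.6% against 5.82%), CAAATA, TTAAAA, AACACT and ATTTTA. CCAGGA was less frequent (0.622% against 3.88%) and the other 9 more frequent. Against a background matched also on GC content, added after the data had been seen, 101 words were more and 111 less frequent, and the AT-rich words no longer led. AAATAT was at 23.7% against 18.8%, and GGCGCC (4.31% against 1.39%), GCGCCA (8.04% against 3.87%) and ACACTG (11.6% against 6.60%) had the smallest p. With that background the calls for TATA box (odds ratio 0.963, adjusted p = 0.707), Ohler motif 1 (1.28, adjusted p = 0.122) and su(Hw) core (1.17, adjusted p = 0.615) ended, and E-box (1.29, adjusted p = 0.00848) and CTCF core (1.31, adjusted p = 0.0365) passed the threshold (Fisher's exact test). For CTCF core this is the opposite direction to its call with replicate 2 alone, so its outcome depended on the setting.

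**Figure D3:**
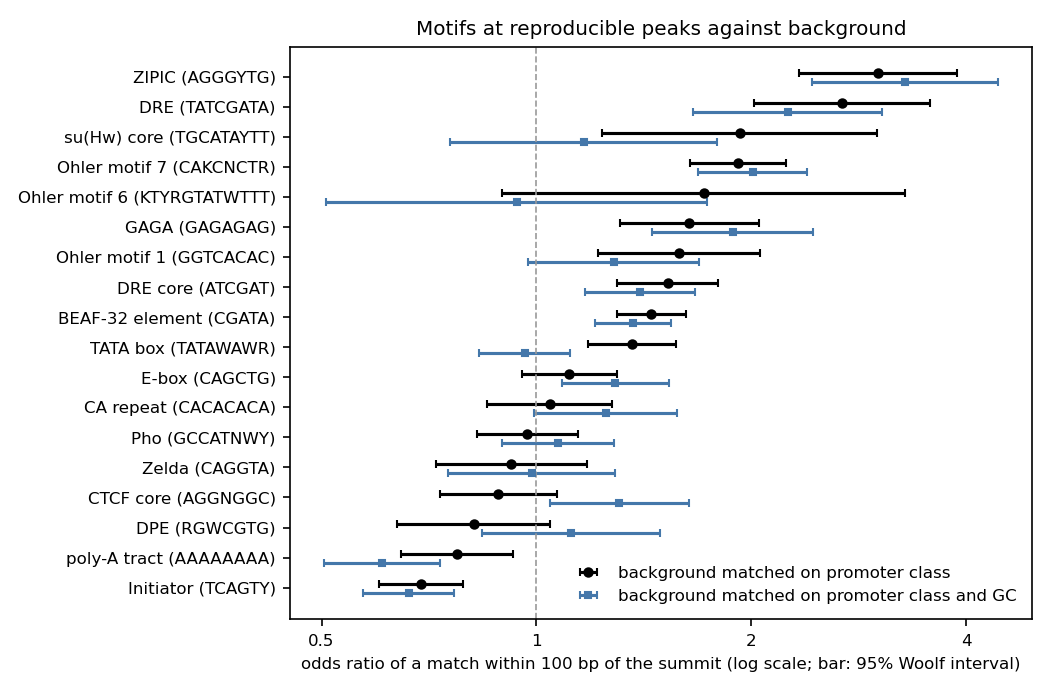
Odds ratio, on a log scale with 95% Woolf intervals, of a motif match within 100 bp of the summit for 2413 reproducible peaks against background matched on promoter class (circles) or on promoter class and GC content (squares). Among the circles ZIPIC (3.01) and the DNA replication-related element (2.68) lie highest and the Initiator (0.689) lowest, and among the squares runs of adenine lie lowest (0.608).

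Peaks were spread over the chromosome arms nearly in proportion to start sites. The X held 338 peaks (14.0% against 16.6% of TSS positions, adjusted p = 0.0037, two-sided exact binomial test) and 3L held 520 (21.5% against 19.3%, adjusted p = 0.0147, exact binomial test). Against sequence length the X was again lower (17.6% of length, adjusted p = 1.5e-05), while 3L did not differ past the threshold (21.0% of length, adjusted p = 0.731, exact binomial test), nor did any other arm. Shares of 2L (19.0%), 2R (20.6%), 3R (24.0%) and chromosome 4 (0.87%, 21 peaks) did not differ past the threshold (adjusted p = 0.673, 0.98, 0.673 and 0.673, exact binomial test). Neither the X nor the 3L difference passed in the stronger part of the list (1207 peaks, adjusted p = 0.605 for each, exact binomial test). With replicate 1 alone 3R was higher (25.5%, adjusted p = 0.0198), and with replicate 2 alone chromosome 4 (1.24%, adjusted p = 0.0282, exact binomial test). Against length, chromosome 4 was lower with replicate 1 alone (0.456% against 1.01%, adjusted p = 0.0122) and 2R higher with replicate 2 alone (20.9% against 18.9%, adjusted p = 0.0404, exact binomial test). Chromosome 4 differed between the replicate lists, with 91 candidate regions in replicate 1 and 583 in replicate 2 (p = 1.3e-89, Fisher's exact test, over regions of 2 libraries and not over replicates).

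At the locus of the tagged gene, BuGZ (FBgn0032600; 2L, 16743405 to 16753704, plus strand), a reproducible peak of signal value 177 covered 16743106 to 16743198, in the promoter shared with the divergent gene LSm7, which encodes an RNA-binding Sm-like protein. It ranked 610 in the reproducible list, 343 in replicate 1 and 1291 in replicate 2. Its summit was 49 bp from the LSm7 TSS and 256 bp from that of BuGZ, just outside the 250 bp window, so BuGZ was not counted among genes with a promoter peak. Within 25 kb of the gene the only other reproducible peak lay in an intron at Cyt-c-p, which encodes cytochrome c (signal value 138). The same span of 60300 bp held 33 pooled candidate regions, 37 of replicate 1 and 49 of replicate 2. The line is described as transgenic, and the lists cannot separate any added tagged copy of the gene from the native one.

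**Figure D4:**
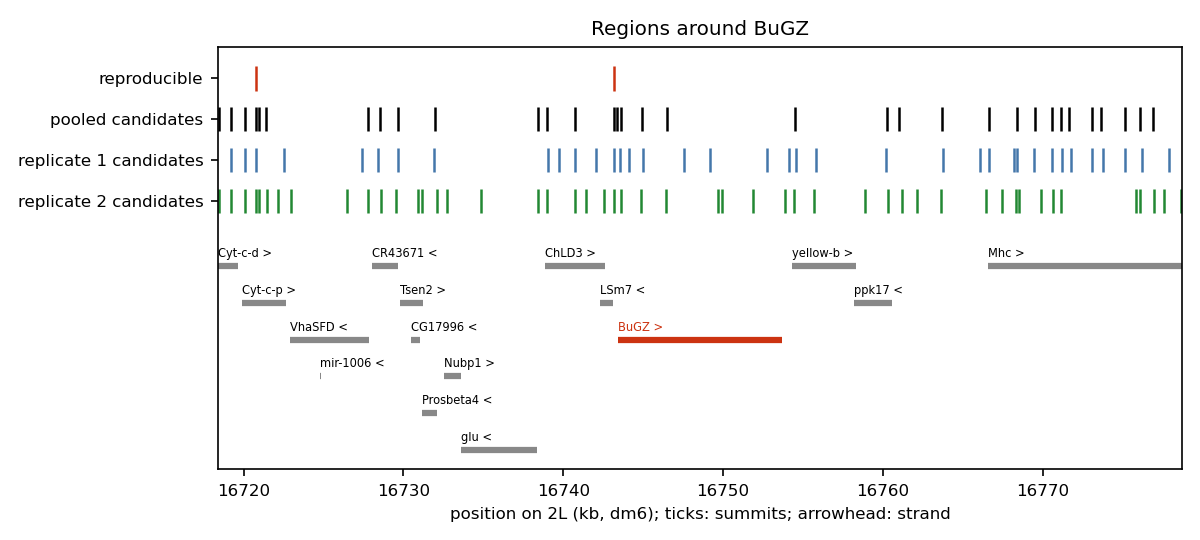
Map of 2L within 25 kb of BuGZ (dm6, position in kb). Ticks mark summits of the 2 reproducible peaks and of 33 pooled, 37 replicate 1 and 49 replicate 2 candidate regions; bars below are annotated genes with their strand, BuGZ in red.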

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

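The background matched on GC, the peaks in the top regions of both replicates, the background promoters for divergent pairs and the classes among non-promoter regions were chosen after the results were seen; all other alternatives were planned. Of 439 recomputed values, 352 kept their side of the threshold, and their direction where the main result had passed it (counts within 1.5 times). Of the rest, 38 no longer passed, 28 newly passed, 13 counts or shares moved and 8 reversed. Direction was compared only where the main result had passed. Changes of direction in other results, such as CTCF core within 50 bp or with GC matched, are therefore not among the 8. The promoter share, the ribosomal protein genes, the GC difference and the divergent pairs kept direction and call under every alternative run. The stronger part of the list held 1207 peaks, with 7 gene lists and 0 chromosome arms (against TSS shares) past the threshold, fewer by construction. The peaks in the top regions of both replicates gave 6 lists and 0 arms. Replicate sharing was 40.5% with summits within 50 bp, 47.9% with 50% reciprocal overlap and 58.6% for the upper part of each top list. Called lists numbered 3 against genes with a candidate region and 6 among protein-coding genes. For snoRNA genes a 1000 bp window gave 21.0%, above other genes and past the threshold; by nearest gene, mitochondrial ribosomal proteins (8.22%) and splicing factors (11.1%) lay below them; the cause was not tested. The odds ratio of poly-A tracts was 1.01 within 250 bp and ranged from 0.724 to 1.02 with either replicate left out, and that of the TATA box was 0.963 with GC matched. That matching used bins of 10 GC bases, and 36 peaks had no matched region but were kept. It therefore lessens differences in base composition and may not remove them. Among non-promoter regions intron (65.1%) and intergenic (25%) shares exceeded the background, as the promoters that lowered them were removed. Words more frequent at peaks numbered 102 for 8 bases and 101 with GC matched. Within 10 kb of BuGZ lay 1 peak. Depth is unknown, so regions below the lists cannot be called absent.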

Other observations

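The tests of distal and promoter motifs, ribosomal protein peaks, symbol families and distal peaks per gene were chosen after the results had been seen. So were those weighing an added BuGZ copy and the ribosomal protein genes, while the count by nearest gene was planned. The 1056 distal peaks, those with no TSS within 250 bp, and the 1357 promoter peaks were each set against background regions of their own kind; differences between these parts were not tested. The extended CTCF site AGRKGGCGC, the fuller sequence known for this insulator protein, lay within 100 bp of 74 distal summits (7.01%) and of 0.284% of distal background regions matched on GC content (3 regions; odds ratio 26.5, 95% Woolf interval 8.31 to 84.2, adjusted p = 7.6e-18, Fisher's exact test). The CTCF core fixed beforehand did not pass at distal peaks (9.09% against 6.53%, odds ratio 1.43, adjusted p = 0.0869, Fisher's exact test). That core, AGGNGGC, cannot match the AGATGGCG form of the site. Despite its name the extended site is thus no mere extension of the core, and the core's result does not bear on that form. At promoter peaks the extended site reached 3.10% against 0.681% (odds ratio 4.66, adjusted p = 1.2e-05, Fisher's exact test). This site and the word CAACACTG were picked from the open search of 8 bases on the same peaks, so their p-values are not independent evidence; AGATGGCG and AGGTGGCG, both part of the site, had odds ratios of 20.7 and 10.3 at distal peaks in that search. GAGA repeats were also enriched at distal peaks (8.90% against 2.46%, odds ratio 3.87, adjusted p = 7.9e-10, Fisher's exact test) and did not differ past the threshold at promoters (5.60% against 5.00%, adjusted p = 0.615, Fisher's exact test). At promoter peaks the sequences with the smallest p were Ohler motif 7 (24.8% against 11.5%), ZIPIC (11.2% against 2.80%) and the word CAACACTG (7.74% against 1.59%, odds ratio 5.19, adjusted p = 7.7e-14, Fisher's exact test). That word matches no listed motif in full, but it differs from Ohler motif 7 (CAKCNCTR) in a single base, so it may not be a separate sequence.

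Promoter peaks of ribosomal protein genes differed in sequence from other promoter peaks. The DNA replication-related element TATCGATA lay at 21 of 77 such peaks (27.3%) against 8.20% of 1280 other promoter peaks (odds ratio 4.20, adjusted p = 4.0e-05, Fisher's exact test), and the BEAF-32 element at 64.9% against 42.5% (adjusted p = 0.00135, Fisher's exact test). The BEAF-32 element CGATA is part of TATCGATA, so these calls are not independent. The core ATCGAT (36.4% against 19.1%, adjusted p = 0.00421) and Ohler motif 6 (5.19% against 1.09%, adjusted p = 0.0461, Fisher's exact test) were also more frequent. The E-box (6.49% against 18.7%, adjusted p = 0.0269), the TATA box (7.79% against 19.5%, adjusted p = 0.0397), the Initiator (6.49% against 17.0%, adjusted p = 0.0461) and GAGA repeats (0 against 5.94%, adjusted p = 0.0473, all Fisher's exact test) were less frequent there, while ZIPIC was at a similar level (10.4% against 11.3%). By nearest gene, whatever the distance and without correction for gene spacing, embryonic patterning genes had a peak at 29.4% (adjusted p = 0.00814, Fisher's exact test). The distal ones lay in introns or beside abd-A, Abd-B, lab, Dfd, dpp, sog, slp2 and hry. The genes sbb, ftz-f1 and for each were nearest to 5 distal peaks. Among 94 families grouped by gene symbol, a set narrowed after a first run to those outside the planned lists, mir genes were lower (5 of 260, adjusted p = 7.7e-05, Fisher's exact test) and the pre-mod(mdg4) transcripts of a single locus higher. For mir genes the annotated 5' end again served as the TSS, without a check that transcription starts there.

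Most ribosomal protein genes carried a peak, and a candidate explanation is that any promoter with a candidate region tends to carry one. Among genes with a candidate region at their promoter, 84 of them ribosomal protein genes, the odds ratio was 22.9 (95% Woolf interval 12.1 to 43.3), down from 43.0 among all genes but still far above 1, which argues against that as the whole cause. Proteasome, oxidative phosphorylation and mitochondrial ribosomal protein genes together had peaks at 36 genes (17.9%), an odds ratio of 19.7 (10.4 to 37.3) for ribosomal protein genes against them. The shares of these 3 lists were known when they were chosen, and translation factors (35.3%) and splicing factors (25%) were left out. The ratio therefore shows a higher share than in these lists, and cannot decide whether housekeeping promoters have a common level. Recovery that rises with accessibility or transcription stays open, since neither was measured here, as does unspecific recovery, since no untagged line was analysed here. No biological explanation was tested, because the design has 1 group.

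Chromosome 4 held 6.51 times the odds of candidate regions in replicate 2 compared with replicate 1 (583 against 91), and the X 1.33 times. Candidate regions of replicate 1 were richer in GC (44.4% ± 6.13 against 42.0% ± 6.32, SD over regions), so base composition may contribute. Within bins of equal GC the odds ratio for chromosome 4 was 4.34 (95% interval 3.45 to 5.45), lower than the crude value but still far above 1, so composition does not account for all of it. Regions within 4 Mb of centromeric ends of the other arms were less frequent in replicate 2 (odds ratio 0.852, interval 0.782 to 0.929), which argues against a general rise near centromeres. The distance was fixed and not taken from a map of heterochromatin, so more signal from heterochromatin itself cannot be decided. A difference in the control alignment or in the stocks stays open, and no biological explanation was tested.

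Candidate regions were dense around BuGZ, where an added copy of the tagged gene might raise coverage. Pooled regions were no denser over the gene and 10 kb on each side than in the 40 kb beyond (rate ratio 0.566, 95% exact interval 0.276 to 1.07). The extent of any copy is not given in the sources used here. The outer part was itself dense (700 regions per Mb against a mean of 218), so a longer copy stays open. Start-site density cannot be told apart from other properties of the region either: of 2884 windows of equal length with a like number of TSS positions, 89.9% held fewer pooled regions than the 33 here, but 98.2% and 99.0% held fewer regions of replicates 1 and 2. The rule set before this count was seen used the pooled list alone and a limit of 95%, under which start-site density would account for the pattern; it was widened to the replicate lists after their counts were seen, and because the lists differ the question is left open, with no biological explanation tested.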
